A study of Drosophila melanogaster with 24 samples.

How the data were processed

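The series measured transcript levels in whole Drosophila melanogaster flies of the LHm population with Affymetrix Drosophila Genome 2.0 arrays, in 24 samples. Per the labels, total RNA was extracted with Trizol and biotinylated cRNA was prepared by the manufacturer's protocol. The deposited values are log2 probe set summaries made with RMA in the affy package, per the submitters' processing notes; the versions, the background and normalization settings and the set of arrays normalized together are not given in the sources used here. The medians of the deposited values were 5.64 to 5.7 in female arrays and 6.82 to 6.91 in male arrays, as would follow from a normalization of each sex on its own, so the balance of male-higher and female-higher genes depends on scaling. The values were used as deposited. Signals near 3 to 4 on the log2 scale are at the level of transcripts absent from a sex, such as Acp26Aa in females with 3.07.

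Groups came from the sample titles: control or MLX, female or male, population 1 to 3 and rep 1 or 2. The titles do not call the reps technical, and they were taken as technical arrays from the study design. The 2 technical arrays of a population and sex were averaged, which left 12 means, and the population was the replicate. After the group means were removed, control and MLX populations with the same number correlated at r = -0.215 to 0.0838 across probe sets. This cannot exclude a pairing, because the sexes of MLX populations, which are linked, correlated at only -0.14 to 0.0922. A block for the number was used only as an alternative, and with it limma called 0 probe sets in females and 0 in males. The female and male means of a population come from the same population and correlated at r = 0.218, 0.12 and 0.153 in control and -0.14, 0.0922 and -0.0448 in MLX populations. The difference in response was fitted on the 12 means without this link, and with each population as a block as an alternative. Of 18952 probe sets, 183 array controls were set aside and 18769 were tested, with no filter on dim signals. By the platform annotation 13647 had 1 gene symbol, 402 several and 4720 none. Symbols were updated through a RefSeq gene table of the assembly Release 6 plus ISO1 MT, in which 13544 probe sets with 1 symbol were found, and chromosomes were taken from it for 13543, 2188 of them on the X. Where a gene had several probe sets, the one with the highest mean over all arrays represented it, which gave 11982 genes.

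Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg over all tested probe sets, threshold 0.05). The 4 groups were fitted together on the 12 means for MLX against control in females, the same in males, the difference between these responses, and the sex difference over both treatments. For the average of the sexes, the female and male values of a population were averaged first and 6 population means were fitted. Unless said otherwise, ± after a group mean is the SD between populations and ± after a change is limma's SE. Counts at an unadjusted p under 0.05 were set beside the number that chance gives on average, which is not a test of the excess. A probe set was counted as without overlap when the 3 MLX populations all lay on 1 side of the 3 control populations.

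The X-linked share was tested with a 2-sided Fisher's exact test over probe sets of known chromosome, at an unadjusted p of 0.01 or less because fewer than 10 probe sets passed the adjusted threshold, and adjusted over 4 comparisons. Sex-bias classes held genes with an adjusted p of 0.05 or less and at least a 2-fold sex difference. They were tested with camera in limma at a preset correlation of 0.01, adjusted over classes and comparisons, and with exact permutation of the 6 populations, which cannot go below p = 0.1 for 3 against 3. The same camera test was run on gene lists fixed before the data were examined, in females, in males and for the difference in response. Of 24 lists, 22 had at least 4 measured genes and were tested, and p was adjusted over 66 tests. The lists covered yolk and fat body, eggshell, ovary germline, accessory gland and seminal fluid, testis and sperm, Y-linked genes, dosage compensation, sex determination, antimicrobial peptides, Turandot stress, heat shock, P450 and glutathione transferase, midgut digestion, photoreceptor and vision, muscle, circadian clock, cuticular hydrocarbon, odorant binding, ribosomal proteins, oxidative phosphorylation, insulin and lipid metabolism, and neuropeptides of mating behaviour. Stellate repeats, with 1 measured gene, and the mitochondrial genome, with 0, were not tested. An estimated correlation between genes was the alternative to the preset one.

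Genes were named by a rule set before the data were examined. For each treatment comparison these were the 10 highest and 10 lowest changes among named, passing probe sets without overlap, or, where fewer than 3 passed in a direction, the 5 with the smallest p without overlap, given as values. The rule also took the 8 highest and 8 lowest sex differences, the members of each list that passed or otherwise the 2 with the smallest p, of which some are given, and a label check on Yp1, Yp2, Yp3, Acp26Aa and Sxl. The genes roX1 and roX2 of that check were not analysed here. CG42594 and the 5 probe sets without a gene name fell outside the rule and were chosen after their values were seen, as they made up the remaining calls.

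The procedure was tested on simulated data built from the measured means and spreads. In the female comparison, with 18769 probe sets, limma recovered 42% of 1.25-fold, 96% of 1.5-fold, 96% of 2-fold and 100% of 3-fold changes, and 5.11% of its calls were false. In the male comparison, with the same 18769 probe sets, it recovered 38%, 88%, 96% and 96%, with 3.05% false. The simulated noise was independent between probe sets, and 50 changes of each size were built in. Measured genes move together and few passed, so these shares test the procedure and may not hold for the measured data.

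Alternatives set before the data were examined were leaving out the dimmest 33.3% of probe sets (mean log2 under 5.07), centring arrays on their medians, quantile normalization within each sex, an intensity trend with robust moderation, 1 probe set per gene, all 24 arrays with a random block, array weights, a replicate block (the population number for comparisons of the treatments, each of the 6 populations for the difference in response and the sex difference), each sex fitted alone, a random population block, a threshold of 0.1, other class and p limits, the estimated correlation, means over a gene's probe sets, and leaving out each population in turn. After seeing the data, leaving out the male arrays with Yp1 above 7 (all of MLX male population 3 and 1 array each of control and MLX male population 2), leaving out the male arrays with poly-A controls below 5, and making sex-bias classes after centring were added. Those limits were set after seeing the arrays. Other splits of the populations into groups of the same size were fitted for each comparison.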

Results

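Transcript levels were measured in whole Drosophila melanogaster females and males of the LHm laboratory population on Affymetrix Drosophila Genome 2.0 arrays. Per the series title, the MLX populations carried X chromosomes that had been subjected to male-limited evolution, and control populations were measured beside them. Each treatment had 3 replicate populations, each population was assayed in both sexes, and each population and sex was put on 2 technical arrays. This made 24 arrays in 4 groups (control females, MLX females, control males and MLX males), and 12 population-by-sex means after the technical arrays were averaged. The population is the replicate (n = 3 per group), and this number limits the precision. The log2 values ran from 2.47 to 15.33. Array medians lay between 5.64 and 5.7 in females and between 6.82 and 6.91 in males. Across probe sets, which are not independent replicates, the technical arrays of a population correlated at r = 0.996 to 0.998, and a female and a male mean at r = 0.687 to 0.716. The median SD was 0.11 on the log2 scale between technical arrays and 0.09 between population means.

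Transcripts with known sex-limited expression were examined first, as a check of the sex labels. The yolk protein gene Yp1 had a log2 signal of 14.93 ± 0.02 (SD, n = 3) in control females and 14.95 ± 0.01 in MLX females, against 5.55 ± 1.03 in control males and 7.00 ± 2.11 in MLX males. Yp2 stood at 15.01 ± 0.04 and 15.06 ± 0.03 in control and MLX females and at 5.61 ± 0.89 and 6.75 ± 1.85 in control and MLX males, and Yp3 at 14.84 ± 0.04, 14.89 ± 0.03, 7.08 ± 0.55 and 7.97 ± 1.24. The seminal fluid gene Acp26Aa had 13.18 ± 0.14 in control males and 13.08 ± 0.09 in MLX males, against 3.07 ± 0.03 and 2.95 ± 0.05 in control and MLX females. The sex determination gene Sxl, which both sexes transcribe, had 9.63 ± 0.12 and 9.71 ± 0.05 in control and MLX females and 8.67 ± 0.06 and 8.82 ± 0.15 in control and MLX males. The wide spread of Yp1 among males came from 4 arrays with Yp1 between 8.09 and 9.17, against 4.50 to 5.86 in the remaining 8 male arrays. These 4 were 1 array of control male population 2, 1 array of MLX male population 2 and both arrays of MLX male population 3. Female arrays had at least 14.91.

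**Figure D1:**
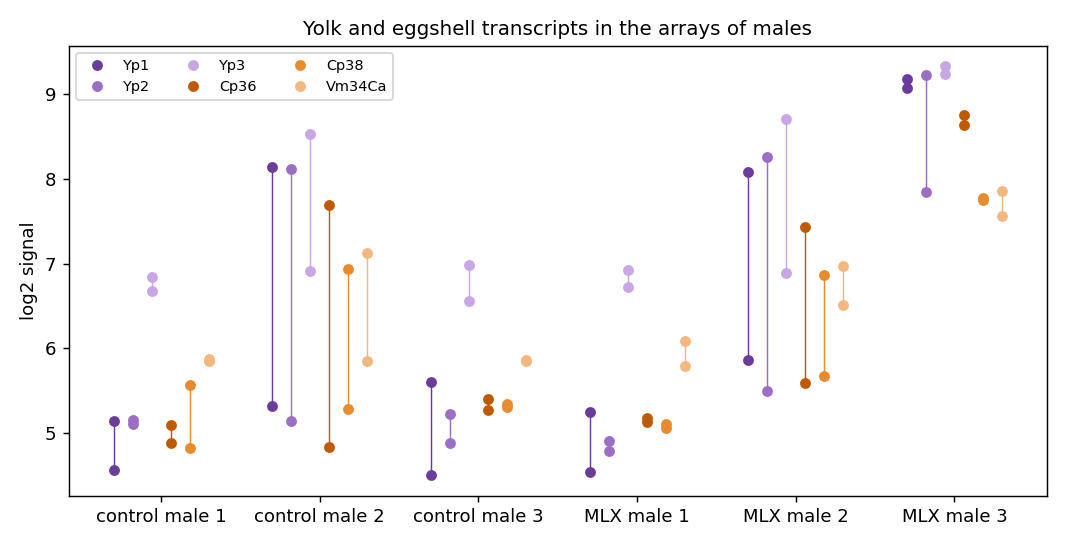
Log2 signal of the yolk genes Yp1, Yp2 and Yp3 and the eggshell genes Cp36, Cp38 and Vm34Ca in each of the 2 technical arrays of the 6 male populations, joined by a line. Yp1 reached 8.09 to 9.17 in 4 arrays, of control population 2, MLX population 2 and MLX population 3, and lay at 4.50 to 5.86 in the other 8.

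The difference between males and females was measured across both treatments. Genes with large differences toward males encode accessory gland proteins or, for EbpII and Ebp, ejaculatory bulb proteins. EbpII differed by 11.42 ± 0.14 (log2 male minus female, SE, 6 populations per sex), Acp98AB by 11.24 ± 0.07, Acp53C14a by 11.17 ± 0.05, Ebp by 11.13 ± 0.16, Acp53Ea by 11.02 ± 0.05, Acp53C14b by 10.87 ± 0.06, Mst57Da by 10.75 ± 0.04 and Acp63F by 10.62 ± 0.04. Their group means in females lay between 3.00 and 3.99, at the level of absent transcripts, so background limits these sizes and their order carries no meaning. Genes with large differences toward females were the germ plasm gene osk (-8.91 ± 0.15), the chorion genes Cp38 (-8.88 ± 0.35), Cp36 (-8.69 ± 0.46) and Cp19 (-8.49 ± 0.32), the yolk genes Yp2 (-8.85 ± 0.49) and Yp1 (-8.67 ± 0.57), and CG43090 (-8.52 ± 0.15) and CG11381 (-8.43 ± 0.08). The sizes for the yolk and chorion genes include the 4 male arrays that carried yolk transcripts, and osk stood at 3.88 ± 0.23 in control males, near background, so this order is not firm either. Of 18769 probe sets, 9366 were higher in males and 6869 higher in females at a limma adjusted p of 0.05 or less, 86.5% of all. The balance between the directions depended on scaling: after each array was centred on its median, the median sex difference moved by -1.19 and the counts were 3568 and 14439. Genes that differed by at least 2-fold at that adjusted p numbered 3702 male-biased and 2710 female-biased of 11982, and 1877 and 6080 after centring.

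In females, the comparison of MLX with control asked how X chromosomes with a history of male-limited evolution went with expression in the other sex. CG10680, on 2L, rose from 9.79 ± 0.04 (SD, n = 3) in control females to 10.22 ± 0.08 in MLX females, a log2 change of 0.42 ± 0.05 (SE, limma adjusted p = 0.0387). CG10514, on 3R, rose from 9.43 ± 0.07 to 9.999 ± 0.07, by 0.57 ± 0.07 (limma adjusted p = 0.0387). CG9897, on 2R, rose from 8.58 ± 0.05 to 9.15 ± 0.14, by 0.57 ± 0.08 (limma adjusted p = 0.0413). A probe set of the X-linked CG42594, chosen after its values were seen, rose from 3.33 ± 0.10 to 3.81 ± 0.03, by 0.47 ± 0.06 (limma adjusted p = 0.0387), close to background. The other probe sets of CG42594 stood at -0.10, 0.00028 and 0.02. The lower values with the smallest p were those of the Pax gene eyg (-0.31 ± 0.05), CG5267 (-0.27 ± 0.05), CG46301 (-0.39 ± 0.07), the bromodomain gene Brd7-9 (-0.26 ± 0.05) and the potassium channel gene Shawl (-0.30 ± 0.06), with limma adjusted p between 0.165 and 0.224. In all, limma called 4 probe sets higher and 0 lower. At an unadjusted p under 0.05 there were 2180, where chance gives 938 on average. MLX and control females did not overlap at 17.3% of probe sets, where chance gives 10% on average. Genes move together, so with 3 populations per group chance alone can give figures far from these averages. The excess here and in the comparisons below is therefore not evidence of a response. The 4 calls depended on every population: 0 remained without control population 1, without control population 3 or without any 1 of the 3 MLX populations, and without control population 2 a single different probe set passed. Across those fits the change of CG10514 stayed between 0.53 and 0.61. Limma called 0 probe sets with arrays centred on their medians, with the dimmest 33.3% left out, with the replicate block and with each sex fitted alone, 22 with array weights and 59 with all 24 arrays.

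In males, the same comparison asked how these X chromosomes went with expression in the sex in which they had evolved. Each of the 5 probe sets that passed was higher in MLX males and carries no gene name here, so they are named by probe. Probe 1641367_at rose from 6.57 ± 0.04 (SD, n = 3) in control males to 7.64 ± 0.10 in MLX males, by 1.07 ± 0.10 (SE, limma adjusted p = 0.00407), and its change in females was -0.01. Probe 1637001_at rose from 4.66 ± 0.07 to 5.67 ± 0.23, by 1.01 ± 0.12 (limma adjusted p = 0.0156). Probes 1624031_at (0.70 ± 0.08), 1623575_at (0.70 ± 0.09) and 1629060_s_at (0.69 ± 0.10) also rose, from levels between 3.19 and 4.10 that are close to background, with limma adjusted p between 0.00959 and 0.045. In females 1637001_at (0.33), 1624031_at (0.25) and 1629060_s_at (0.33) were also higher in MLX without overlap, with limma adjusted p between 0.266 and 0.333, and 1623575_at stood at 0.04. The lower values with the smallest p were those of CG15373 on the X (-0.48 ± 0.07, limma adjusted p = 0.0523), SoYb, a Tudor-domain gene of the piRNA pathway (-0.33 ± 0.05), CG4049 (-0.39 ± 0.07), CG15239 on the X (-0.60 ± 0.11) and CG32121 (-0.31 ± 0.06). The named genes with the smallest p above 0 were CG43066 (0.53 ± 0.08, limma adjusted p = 0.0556), CG11413 (0.43 ± 0.07), CG4911 (0.34 ± 0.06), nAChRalpha4 (0.35 ± 0.07, its other probe set -0.01) and CG5645 (0.29 ± 0.06). Limma called 5 probe sets higher and 0 lower, with 1531 at an unadjusted p under 0.05, where chance gives 938. MLX and control males did not overlap at 13.7% of probe sets, where chance gives 10%. The count was 1 without control population 1, 2 without control population 2, 0 without control population 3, 2 without MLX population 1, 9 without MLX population 2 and 3 without MLX population 3. Without control population 3 the changes of the 5 probe sets were 0.64 to 1.06, and each SE was larger with fewer populations (0.09 to 0.14, against 0.08 to 0.12). Without the 4 arrays that carried yolk transcripts, a choice made after seeing the data, limma called 2 higher and 7 lower. That choice removes MLX male population 3 and leaves control male population 2 and MLX male population 2 on 1 array each, so it mixes the effect of these transcripts with that of fewer populations, here and below.

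**Figure D2:**
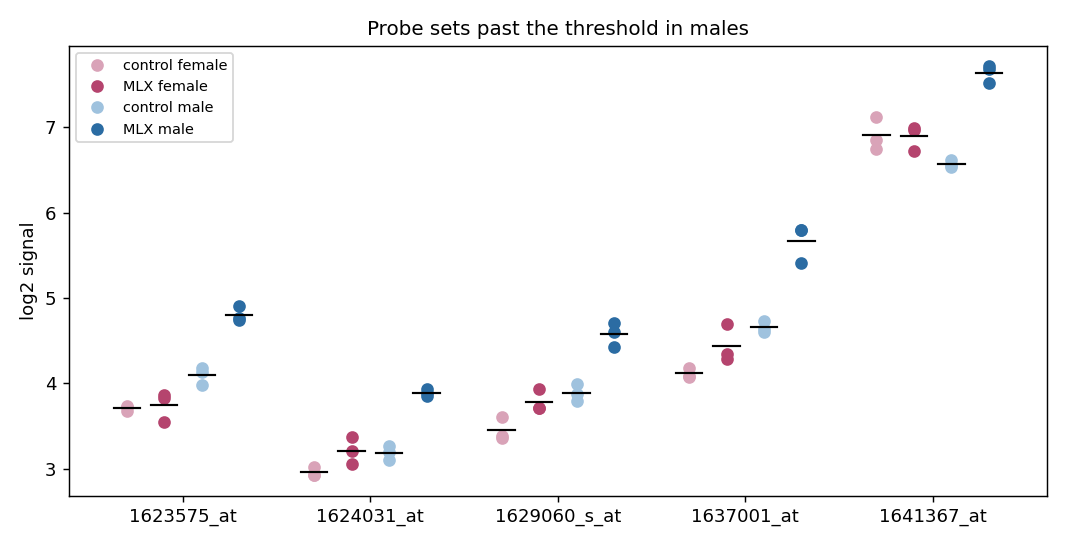
Log2 signal of the 5 probe sets past the threshold in males, as points for the 3 populations of each of the 4 groups with a line at the group mean. The 3 MLX male populations lie above the 3 control male populations for each probe set, and for 1641367_at the means are 7.64 and 6.57.

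The 2 sexes of a population were averaged to find changes that they share. No gene passed in this comparison, so the following are values. The kinase gene Takl2 stood at -0.38 ± 0.04 (log2 MLX minus control, SE, n = 3), CG15239 at -0.38 ± 0.05, SoYb at -0.24 ± 0.04, CG5267 at -0.25 ± 0.04 and Brd7-9 at -0.25 ± 0.04. CG6495 stood at 0.29 ± 0.04, CG43066 at 0.45 ± 0.06, Dyro at 0.31 ± 0.04, the juvenile hormone binding protein gene Jhbp14 at 0.34 ± 0.05 and nAChRalpha4 at 0.33 ± 0.05. Their limma adjusted p lay between 0.134 and 0.279, and the smallest of any probe set was 0.0766. Limma called 0 probe sets, with 2141 at an unadjusted p under 0.05, where chance gives 938. It called 15 with the population as a random block, 222 with all 24 arrays and 2 without MLX population 2. The fit of all 24 arrays, here and in the other comparisons, draws its spread in part from technical arrays. For the average it also takes the 2 sexes of a population as independent, so the 222 overstates the evidence. MLX and control did not overlap at 17.8% of probe sets, where chance gives 10%. Across 11982 genes, which are not independent replicates, the MLX change in females correlated with that in males at r = 0.20 (Spearman's rho = 0.195), and 57.5% had the same sign. The highest r among the other 9 ways of splitting the 6 populations was 0.186. With 10 splits the share cannot go below 0.1.

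Whether the response differed between the sexes was tested as the MLX change in males minus that in females. CG10514, raised in MLX females, was 12.05 ± 0.10 (SD, n = 3) in control males and 11.91 ± 0.12 in MLX males, and its responses differed by -0.71 ± 0.10 (SE, limma adjusted p = 0.213). Other values below 0 were those of CG9664 (-0.58 ± 0.12), CG13982 (-0.48 ± 0.10), CG15373 (-0.46 ± 0.10) and the phosphatase gene Mipp1 (-0.43 ± 0.09). Above 0 stood CG12912 (0.43 ± 0.09), CG4911 (0.40 ± 0.09), CG3457 on the X (0.36 ± 0.08), CG10383 (0.35 ± 0.08) and CG43084 (0.34 ± 0.07). For these 9 the limma adjusted p was 0.773, and the smallest of any probe set was 0.127. Limma called 0 probe sets, with 1180 at an unadjusted p under 0.05, where chance gives 938. It called 2 with an intensity trend, 1 with array weights and 0 with each population as a block, which compares the sexes within populations. The response did not overlap at 12.4% of probe sets, where chance gives 10%. The changes that passed in females or in males alone were therefore not shown to differ between the sexes.

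Because the X was the chromosome under selection, X-linked probe sets were compared with those of other chromosomes. Too few passed the adjusted threshold, so the test ran at an unadjusted p of 0.01 or less. In males 67 of 2188 X-linked probe sets were at that p (3.06%), 30 of them higher and 37 lower in MLX, against 248 of 11355 elsewhere (2.18%). Fisher's exact test gave an odds ratio of 1.41 (95% interval 1.06 to 1.87, p = 0.0161, and 0.0643 adjusted over 4 comparisons). In females the X-linked share was 69 of 2188 (3.15%) against 423 of 11355 (3.73%), an odds ratio of 0.842 (Fisher's exact p = 0.212). The odds ratio was 1.06 (Fisher's exact p = 0.676) for the average of the sexes and 0.669 (Fisher's exact p = 0.126) for the difference in response. Both turned without single populations, with Fisher's exact p above 0.05 throughout. For the average it was 0.835, 0.873 and 0.919 without control populations 1, 2 and 3, and 0.848 and 0.767 without MLX populations 1 and 3. For the difference in response it was 1.02 without control population 2 and 1.24, 1.30 and 1.22 without MLX populations 1, 2 and 3. At an unadjusted p of 0.05 or less the odds ratio was 1.23 in males (adjusted p = 0.0383) and 1.07 in females (Fisher's exact p = 0.307). At 0.01 or less it was, in males, 1.2 (Fisher's exact p = 0.359) without control population 1 and 1.30 (0.0877) without control population 3. It was 1.33 (0.0615) without MLX population 2 and 1.11 (0.576) without MLX population 3. The unadjusted p was under 0.05 without control population 2 (1.62, Fisher's exact p = 0.0063) and MLX population 1 (1.34, 0.0307). It was so too with 1 probe set per gene (1.51, 0.00796) and without the dimmest probe sets (1.42, 0.0238). Without the arrays that carried yolk transcripts, a choice made after seeing the data, the odds ratio was 1.29 (0.0388). Fisher's test takes probe sets as independent, although genes move together and a gene can have several. Leaving MLX population 3 out gave 0.771 in females (Fisher's exact p = 0.0445). X-linked genes as a whole were not shifted: over 1873 genes the mean log2 change was -0.010 in females and -0.0035 in males, with a camera adjusted p of 0.734 in each comparison.

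Male-biased and female-biased genes were compared as classes, to see whether expression had moved toward one sex. In MLX females the 3702 male-biased genes had a mean log2 change of 0.039, with 57.3% above 0 (camera adjusted p = 1.1e-06), and the 2710 female-biased genes one of -0.055, with 23.5% above 0 (camera adjusted p = 8.1e-10). Neither passed with an estimated correlation (adjusted p = 0.246 for each). The poly-A controls, bacterial transcripts added to the RNA, were 0.45 higher in the same MLX females without overlap, so a difference in RNA input or labelling stays open here, as does a smaller share of ovary. In MLX males the male-biased genes had -0.017 (camera adjusted p = 0.151) and the female-biased genes 0.017 (camera adjusted p = 0.0253, and adjusted p = 0.627 with an estimated correlation). Averaged over the sexes the means were 0.011 for male-biased genes (camera adjusted p = 0.0253) and -0.019 for female-biased genes (camera adjusted p = 0.0137), each with an adjusted p = 0.627 with an estimated correlation. The response of males minus that of females was -0.055 in male-biased genes (camera adjusted p = 1.1e-07) and 0.072 in female-biased genes (camera adjusted p = 2.2e-12). Both had an adjusted p = 0.246 with an estimated correlation. They include the change in females, so RNA input or labelling stays open for them as well. Per population, the male minus female difference of the male-biased class was 3.17 ± 0.02 (SD, n = 3) in MLX and 3.23 ± 0.05 in control, and that of the female-biased class -2.05 ± 0.02 and -2.12 ± 0.05. A 2-sided exact permutation test gave p = 0.2 for each class, where 3 against 3 cannot go below 0.1. In the alternatives that follow, a call of a class rests on its unadjusted camera p. In females the male-biased class was 0.018, still past the threshold, without control population 2, and turned to -0.00054 with classes of at least 4-fold and to -0.014 with classes made after centring. Without control population 2 the female-biased class stood at -0.028 in females, and without control population 3 at -0.082, both past the threshold. The difference in response of the male-biased class was -0.026, also past it, without control population 2. In males the female-biased class lost its call without control population 3 (0.015) and without MLX population 3 (0.0078). It also lost it without the 4 male arrays that carried yolk transcripts (0.0091), without the 2 male arrays that lacked poly-A controls (0.0040) and with classes made after centring (0.0061), all choices made after seeing the data. In males the male-biased class gained a call without control population 1 (-0.034) and without MLX population 1 (-0.035), and turned to 0.0074 without the 4 arrays that carried yolk transcripts. The averaged calls were lost without control population 1 (male-biased 0.0053), control population 2 (0.0054, female-biased -0.0029) and MLX population 1 (-0.0017, female-biased -0.011). The averaged male-biased mean was 0.023 without control population 3 and 0.018 without MLX population 3, and the female-biased mean was -0.034 without control population 3. Without the 4 arrays that carried yolk transcripts the averaged male-biased mean was 0.026, also past the threshold.

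Gene lists fixed beforehand were tested next, first in females. Muscle genes were higher in MLX females: the mean log2 change of 21 genes was 0.31, with 21 above 0 (camera adjusted p = 9.2e-12, but adjusted p = 0.736 with an estimated correlation). The poly-A controls were also 0.45 higher in these females, without overlap, so for this and the other lists in females a difference in RNA input or labelling cannot be told apart from the treatment. The titin-like gene sls stood at 7.64 ± 0.05 (SD, n = 3) in control and 8.2 ± 0.20 in MLX females, a change of 0.55 ± 0.11 (SE), with 0.35 and 0.10 in its other probe sets, and the troponin C gene TpnC41C at 9.58 ± 0.09 and 9.93 ± 0.09. Genes of photoreceptors and vision were also higher, with a mean of 0.12 over 23 genes and 21 above 0 (camera adjusted p = 5.8e-05, but adjusted p = 0.736 with an estimated correlation). The phosphatidylinositol transfer gene rdgB changed by 0.31 ± 0.07 (its other probe set by -0.07) and the channel gene trpl by 0.23 ± 0.06. For muscle 6 genes were higher adjusted over the list alone, and for vision 2, against 0 for either over all genes. Without each population in turn the muscle mean stayed between 0.23 and 0.43 and past the threshold, and so did vision, with 0.07 (camera adjusted p = 0.0116) without control population 2. List means per population overlapped: muscle stood at 9.60 in MLX female population 3, within the 9.38 to 9.70 of control females. That population also had the lowest poly-A controls of the MLX females (6.6). Control population 3, with the highest muscle mean of control females, had their highest poly-A controls (6.44). The order did not match throughout: MLX population 2 had the highest poly-A controls (6.96), but MLX population 1 the highest muscle mean. Whether muscle and poly-A controls go together across populations was not tested.

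Another 6 lists passed in females with smaller changes. Oxidative phosphorylation genes had a mean of 0.050 over 76 genes, with 62 above 0 (camera adjusted p = 0.0015), cytochrome P450 and glutathione transferase genes 0.09 over 79, with 58 above 0 (camera adjusted p = 0.0047), and odorant binding protein genes 0.10 over 43, with 30 above 0 (camera adjusted p = 0.0166). With an estimated correlation the adjusted p of these 3 lists was 0.951, 0.941 and 0.941. Neuropeptides and receptors of mating behaviour had 0.07 over 25 genes, with 16 above 0 (camera adjusted p = 0.0373), and insulin and lipid metabolism 0.046 over 25, with 17 above 0 (camera adjusted p = 0.0378), each with an adjusted p = 0.736 with an estimated correlation. Accessory gland and seminal fluid genes had -0.08 over 34, with 25 below 0 (camera adjusted p = 0.0292, but adjusted p = 0.941 with an estimated correlation), at a background level of 4.07 in control females. Adjusted over the list alone, 1 P450 or glutathione transferase gene and 1 neuropeptide or receptor gene were higher and 0 genes of the other 4 lists passed, against 0 for each over all genes. Members with the smallest p were Cyp4e1 (0.41 ± 0.08) and GstS1 (0.22 ± 0.08), the X-linked sex peptide receptor gene SPR (0.57 ± 0.11, its other probe set 0.08) and Gr68a (-0.18 ± 0.06), ND-24L (-0.20 ± 0.06) and ATPsynbetaL (-0.15 ± 0.05), Obp19c (-0.22 ± 0.08) and Obp18a (0.29 ± 0.12), ACC (0.18 ± 0.07) and Desat1 (0.15 ± 0.05), and Acp29AB (0.21 ± 0.06) and Dup99B (-0.25 ± 0.08). Oxidative phosphorylation lost its call without control population 1 (0.030), control population 2 (0.025) or MLX population 1 (0.015), and had 0.095 without control population 3 and 0.082 without MLX population 3. The P450 list lost it without control population 2 (0.0028) or MLX population 1 (0.035) and had 0.15 without control population 1 or MLX population 3, and odorant binding lost it without control population 2 (0.038). The accessory gland list lost it without control population 1 (-0.06), control population 3 (-0.049) or MLX population 2 (-0.07) and had -0.12 without control population 2. Insulin and lipid metabolism lost it without control population 1 (0.06), control population 2 (0.047) or MLX population 2 (0.013), and with means over a gene's probe sets (0.041, camera adjusted p = 0.0511). Neuropeptides lost it without control population 2 (0.046), control population 3 (0.07), MLX population 1 (0.05) or MLX population 3 (0.07).

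**Figure D3:**
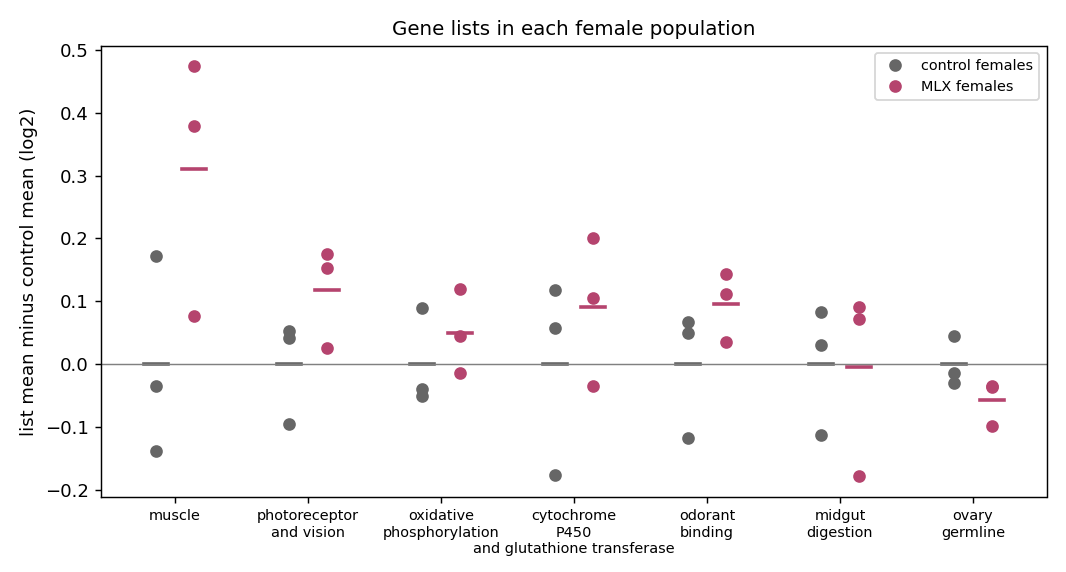
Mean log2 signal of 7 gene lists in each female population, minus the mean of the 3 control populations, with points for populations and lines for group means. The muscle mean lies 0.31 above control, and the MLX population nearest to control lies within the control range.

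The remaining 14 tested lists did not pass in females. Ovary germline genes had a mean log2 change of -0.06 over 35 genes (camera adjusted p = 0.0715), with -0.17 ± 0.07 for zuc and -0.15 ± 0.07 for BicC. That list passed without control population 3 (-0.07, camera adjusted p = 0.0462) and without MLX population 2 (-0.07, camera adjusted p = 0.0388), and with means over a gene's probe sets (-0.06, camera adjusted p = 0.0482). Heat shock genes had -0.11 over 6 (camera adjusted p = 0.207), circadian clock genes 0.07 over 10 (camera adjusted p = 0.153) and cuticular hydrocarbon genes 0.0084 over 16 (-0.0075 after centring, camera adjusted p = 0.188), which reached 0.06 (camera adjusted p = 0.0257) without control population 3. Antimicrobial peptide genes had 0.049 over 20 (camera adjusted p = 0.421), and 0.16 (camera adjusted p = 0.0203) without control population 1. That population had a list mean of 8.25, above the 8.05 to 8.10 of MLX females, and control populations 2 and 3 (7.88 and 7.93) lay below them. Testis and sperm genes had -0.031 over 51, yolk and fat body genes 0.16 over 4, Turandot stress genes -0.16 over 5, dosage compensation genes 0.014 over 7 (-0.0018 after centring), sex determination genes -0.024 over 17 and midgut digestion genes -0.0056 over 40, with camera adjusted p between 0.382 and 0.995. For 3 lists the mean, the median and the direction of the test differed in sign: eggshell (mean -0.06, median -0.11, test upward, 19 genes), Y-linked (mean -0.012, median 0.0043, test upward, 7 genes) and ribosomal proteins (mean -0.00084, or 0.0015 after quantile normalization, median 0.00091, test upward, 41 genes), with camera adjusted p = 0.738, 0.995 and 0.738. Adjusted over the list alone, 1 eggshell and 1 sex determination gene were higher, against 0 over all genes. The members with the smallest p included the eggshell gene CG13992 (0.34 ± 0.07), the sex determination genes her (0.33 ± 0.07) and dsx (0.31 ± 0.09) and the testis list genes achi (0.26 ± 0.07) and S-Lap8 (-0.26 ± 0.08). With an estimated correlation the adjusted p of these 14 lists lay between 0.736 and 0.997.

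In males the accessory gland and seminal fluid genes were lower in MLX. Their mean log2 change was -0.11 over 34 genes, with 27 below 0 (camera adjusted p = 0.000107, but adjusted p = 0.736 with an estimated correlation), from a list mean of 12.4 in control to 12.3 in MLX males. List means per population overlapped: MLX male population 2 stood at 12.387, within the 12.381 to 12.544 of control males. The list had -0.08 in females, where it lay at background, and its difference in response did not pass (camera adjusted p = 0.455). Acp62F stood at 13.63 ± 0.07 (SD, n = 3) in control and 13.27 ± 0.16 in MLX males, a change of -0.36 ± 0.08 (SE). Acp36DE, whose product acts in sperm storage, stood at 14.16 ± 0.04 and 13.90 ± 0.09, a change of -0.27 ± 0.06. Adjusted over the list alone 6 genes of this list were lower, against 0 over all genes. Eggshell genes were higher, with a mean of 0.39 over 19 genes (camera adjusted p = 0.000168), as were yolk and fat body genes, with 0.94 over 4 (camera adjusted p = 0.0378). With an estimated correlation their adjusted p was 0.906 and 0.886. Oxidative phosphorylation genes had 0.037 over 76, with 50 above 0 (camera adjusted p = 0.0326, but adjusted p = 0.997 with an estimated correlation). In these 3 lists 0 genes passed adjusted over the list alone, and 0 over all genes. The accessory gland list stood at -0.06 without control population 3 (camera adjusted p = 0.0502) and passed without each other population. The eggshell mean was 0.032 (camera adjusted p = 0.794) without MLX population 3 and 0.68 without MLX population 1. The yolk mean was 0.25 without MLX population 3, 0.68 without control population 3, 0.82 without control population 1 and 0.95 without MLX population 2, none of which passed, and 1.63 without MLX population 1. Oxidative phosphorylation lost its call without control population 3 (0.014), MLX population 2 (0.029) or MLX population 3 (0.024), and had 0.06 without MLX population 1. It also lost it without the arrays that lacked poly-A controls (0.029, camera adjusted p = 0.0615). Without the 4 arrays that carried yolk transcripts the eggshell, yolk and oxidative phosphorylation lists did not pass (0.041, 0.16 and 0.0052), while the accessory gland list stood at -0.21 (camera adjusted p = 1.6e-09).

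The other 18 lists did not pass in males. Midgut digestion genes had a mean of -0.15 over 40 genes, with 35 below 0 (camera adjusted p = 0.0649), and passed without control population 3 (-0.19), MLX population 2 (-0.25) or MLX population 3 (-0.26), and with the replicate block (-0.15, camera adjusted p = 0.0457). Only MLX male population 1 (list mean 10.16) lay low. MLX male populations 2 and 3 (10.79 and 10.81) lay within the 10.66 to 10.83 of control males. Ovary germline genes had 0.06 over 35 (camera adjusted p = 0.0889) and passed without control population 2 (0.08), MLX population 1 (0.08) or MLX population 2 (0.08). For this list only MLX male population 3 (list mean 6.599), whose arrays carried yolk transcripts, lay above control males. MLX male populations 1 and 2 (6.451 and 6.457) lay within the 6.397 to 6.49 of control males. Antimicrobial peptide genes had 0.13 over 20 (camera adjusted p = 0.0923) and passed without control population 1 (0.24) or MLX population 1 (0.19), with 1 gene, pirk (0.31 ± 0.07), higher adjusted over the list alone against 0 over all genes. Muscle genes had 0.11 over 21 (camera adjusted p = 0.369), and 0.17 (camera adjusted p = 0.000976) without MLX population 3. Photoreceptor and vision genes had -0.029 over 23 (camera adjusted p = 0.92), with 1 gene, chp (-0.31 ± 0.07), lower adjusted over the list alone against 0 over all genes. P450 and glutathione transferase genes had 0.028 over 79 (camera adjusted p = 0.455) and 0.09 without MLX population 1 (camera adjusted p = 0.000766), and odorant binding genes -0.015 over 43 (camera adjusted p = 0.58) and -0.07 without MLX population 2 (camera adjusted p = 0.0343). Insulin and lipid metabolism genes had -0.06 over 25, with -0.23 ± 0.06 for Ilp5 and 0.42 ± 0.13 for the insulin receptor gene InR, and neuropeptides 0.014 over 25, with 0.39 ± 0.11 for SPR (its other probe set -0.02). The means were 0.012 for Y-linked genes, 0.0022 for dosage compensation (-0.00012 after centring and -0.00079 after quantile normalization), 0.0038 for sex determination, -0.09 for Turandot stress, -0.05 for circadian clock, -0.028 for cuticular hydrocarbon and 0.0054 for ribosomal protein genes. Testis and sperm genes (mean -0.0038, median -0.0097, test upward, 51 genes) reached -0.06 without MLX population 1 (camera adjusted p = 0.0442), and heat shock genes had a mean of -0.0065 with a median of 0.028 and a downward test over 6 genes. For these last 11 lists the camera adjusted p lay between 0.455 and 0.979. Without the 4 arrays that carried yolk transcripts, Y-linked (0.13, camera adjusted p = 0.019), testis and sperm (0.06, camera adjusted p = 0.0131) and midgut digestion genes (-0.21, camera adjusted p = 0.0275) passed. Without the arrays that lacked poly-A controls, antimicrobial peptide genes passed (0.09, camera adjusted p = 0.0487). With an estimated correlation the adjusted p of all 18 lists lay between 0.941 and 0.997.

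**Figure D4:**
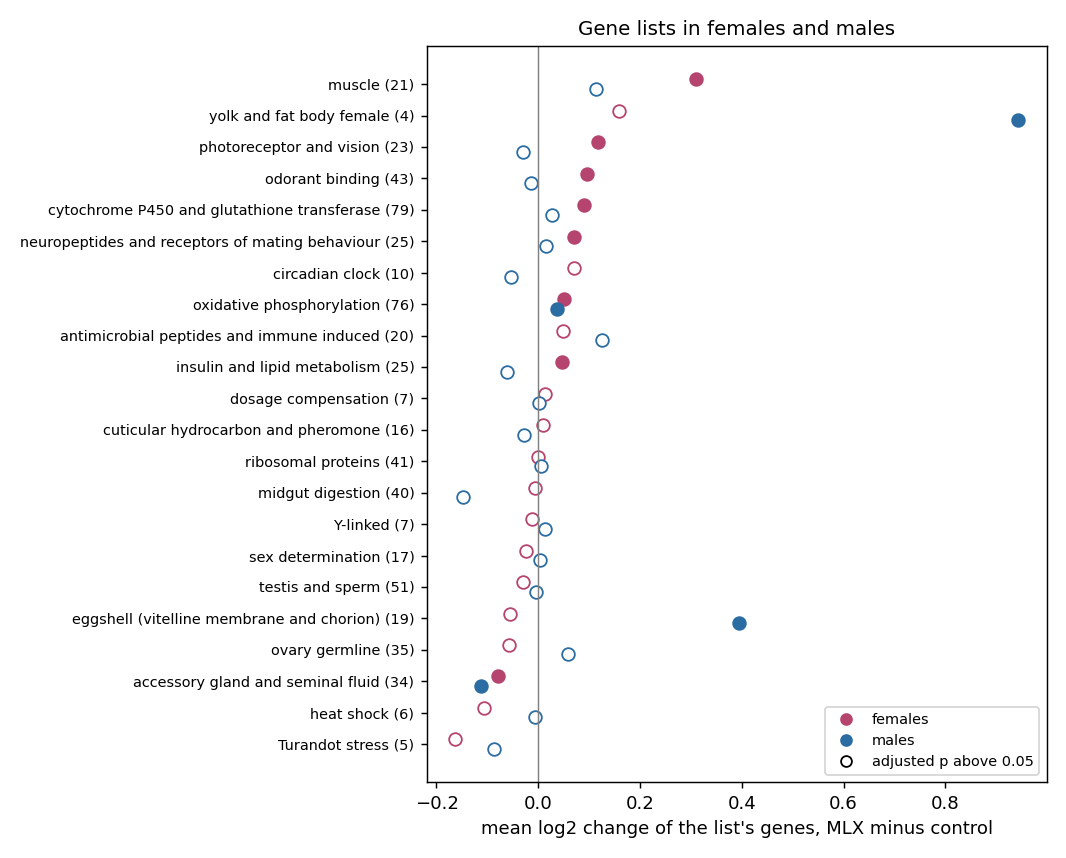
Mean log2 change of each gene list, MLX minus control, in females and males, with the number of measured genes in brackets. Filled points mark a camera adjusted p of 0.05 or less, and the muscle list in females lies at 0.31.

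The same lists were tested for a difference in response between males and females. This difference includes the MLX change in females, where the poly-A controls were 0.45 higher, against a change of -0.12 in males. A difference in RNA input or labelling therefore cannot be told apart from the treatment here either. Muscle genes responded less in males, by a mean of -0.20 over 21 genes, with 19 below 0 (camera adjusted p = 7.4e-07, but adjusted p = 0.736 with an estimated correlation). The projectin gene bt differed by -0.33 ± 0.12 (SE, n = 3) and TpnC41C by -0.29 ± 0.11. Photoreceptor and vision genes differed by -0.15 over 23, with 21 below 0 (camera adjusted p = 0.000168, but adjusted p = 0.736 with an estimated correlation), among them trpl by -0.27 ± 0.08 and rdgB by -0.29 ± 0.10 (its other probe set by 0.05). Odorant binding genes differed by -0.11 over 43, with 32 below 0 (camera adjusted p = 0.0107, but adjusted p = 0.933 with an estimated correlation), and a10 by -0.30 ± 0.09. Ovary germline genes differed by 0.12 over 35, with 25 above 0 (camera adjusted p = 0.00331, but adjusted p = 0.78 with an estimated correlation), and tej by 0.27 ± 0.10. Without the 4 arrays that carried yolk transcripts the ovary germline mean fell to 0.07 (camera adjusted p = 0.0275). In these 4 lists 0 genes passed adjusted over the list alone, and 0 over all genes. The muscle list kept its call without each population, with -0.12 without control population 2 and -0.31 without control population 3, and so did vision, with -0.09 without MLX population 1 and -0.23 without MLX population 3. Odorant binding lost its call without control population 1 (-0.10), control population 2 (-0.07) or MLX population 1 (-0.023), and without the arrays that lacked poly-A controls (-0.09, camera adjusted p = 0.0961).

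For the other 18 lists the difference in response did not pass. Eggshell genes differed by 0.45 over 19 (camera adjusted p = 0.0511), insulin and lipid metabolism genes by -0.11 over 25 (camera adjusted p = 0.0681), P450 and glutathione transferase genes by -0.06 over 79 (camera adjusted p = 0.102) and neuropeptides by -0.06 over 25 (camera adjusted p = 0.115). Midgut digestion genes differed by -0.14, yolk genes by 0.78, circadian clock genes by -0.12, heat shock genes by 0.10, antimicrobial peptide genes by 0.08, Turandot stress genes by 0.08 and cuticular hydrocarbon genes by -0.037. Testis and sperm genes differed by 0.027, sex determination genes by 0.027, Y-linked genes by 0.024, ribosomal protein genes by 0.0063, oxidative phosphorylation genes by -0.012 (0.0011 after centring) and accessory gland genes by -0.034. Dosage compensation genes had a mean of -0.012 (0.0017 after centring) with a median of 0.025 and an upward test over 7 genes. Adjusted over the list alone, 1 accessory gland gene, Acp29AB (-0.39 ± 0.09), was lower, against 0 over all genes. The camera adjusted p of these 18 lists lay between 0.0511 and 0.995, and with an estimated correlation the adjusted p lay between 0.736 and 0.997. Without a single population some of these lists passed. Eggshell did so without control population 2 (0.54), MLX population 1 (0.72) or MLX population 2 (0.54), yolk without MLX population 1 (1.51) and midgut digestion without MLX population 3 (-0.34). The P450 list did so without control population 1 (-0.10), control population 3 (-0.11), MLX population 2 (-0.07) or MLX population 3 (-0.17), and neuropeptides without control population 1 (-0.08) or MLX population 2 (-0.09). Oxidative phosphorylation (-0.08 and -0.06) and insulin and lipid metabolism (-0.13 and -0.14) did so without control population 3 and without MLX population 3, and cuticular hydrocarbon genes without control population 3 (-0.09). The eggshell and yolk differences depend on MLX population 3, whose male arrays carried yolk transcripts. Without it the male changes were 0.032 and 0.25, against 0.39 and 0.94. The midgut difference depends on MLX male population 1 (list mean 10.16, against 10.79 and 10.81 in MLX male populations 2 and 3). Without the 4 arrays that carried yolk transcripts, accessory gland (-0.13, camera adjusted p = 0.00132), testis and sperm (0.10, 0.00167), Y-linked (0.14, 0.0498), P450 and glutathione transferase (-0.10, 0.0275) and insulin and lipid metabolism genes (-0.12, 0.019) passed. Eggshell genes passed without the arrays that lacked poly-A controls (0.48, camera adjusted p = 0.0318) and with each population as a block (0.45, camera adjusted p = 0.0288).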

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

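The tests on yolk transcripts in male arrays, on muscle genes and on poly-A controls were chosen after the result was seen, and so was the first test on probe sets without a gene name, while the median over all of them was set as a test before its value was seen.

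Single arrays lay far from the other 5 of their group. In control male population 2, array 1 had Yp1 at 8.14 (next highest 5.61), Yp2 at 8.12 (next 5.22) and Yp3 at 8.53 (next 6.99). The poly-A controls, bacterial transcripts added to the RNA, stood at 4.10 in array 1 of control male population 1 (next lowest 6.34) and at 3.999 in array 2 of MLX male population 3 (next 6.23). Of 28 such group tests, 5 array values stood out, where chance picks about 1 in 20, or 1.4. The tests are not independent, as Yp1, Yp2 and Yp3 stood out in the same array and arrays of a population are paired. The 1.4 is therefore no test of an excess. The poly-A controls lie outside the main measurement and differed between the female groups, at 6.81 ± 0.19 (SD, n = 3) in MLX and 6.37 ± 0.06 in control females, by 0.45 (exact permutation p = 0.1, the smallest possible). Responses of the sexes differed by test, males minus females, in the muscle list (-0.20), the photoreceptor and vision list (-0.15), the odorant binding list (-0.11), the ovary germline list (0.12), male-biased genes (-0.055) and female-biased genes (0.072). With an estimated correlation none of these 6 passed. Each includes the MLX change in females, so the poly-A difference in females limits them too.

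Yolk and eggshell transcripts in 4 male arrays (1 of control population 2, 1 of MLX population 2 and both of MLX population 3) may stem from RNA of females in those samples. Of 10 other genes abundant in females, a share of 70%, 60%, 100% and 90% lay above every remaining male array, so the lowest was 60% against a bound of 50%, on genes with a female mean of at least 12, a limit lowered from 13 after that had left at most 1 gene. Against yolk genes being switched on in the males themselves, eggshell genes exceeded the remaining male arrays by at least 0.61 (SD 0.07). Against female transcripts in the RNA before it was divided, the 2 arrays differed in the eggshell mean by 0.78 in control population 2 and by 0.49 in MLX population 2, where populations without them differed by at most 0.12, whereas the 2 arrays of MLX population 3 both carried them and differed by 0.045, as such an origin would give. That test takes the 2 arrays of a population as made from 1 RNA sample, which the titles do not say. On the values as deposited, the Yp1 excess was 0.755% to 1.73% of the female level. The sexes were not put on 1 scale for this, and a shift by the array medians would lower these shares. The step at which such RNA entered remains open.

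Muscle genes were higher in MLX females, by a mean of 0.31, with a candidate explanation in a smaller share of ovary in whole flies. That would raise other somatic tissues alike, and the means were 0.31 ± 0.17 (SD over 21 genes) for muscle, 0.12 ± 0.10 for vision, 0.10 ± 0.17 for odorant binding, 0.09 ± 0.21 for P450 and glutathione transferase and -0.0056 ± 0.20 for midgut genes. Muscle minus the mean of the other 4 lists was 0.23 higher in MLX than in control female populations (1.91 ± 0.11 and 1.67 ± 0.12, SD, n = 3, exact permutation p = 0.2, where the smallest possible is 0.1), too few populations to decide, so ovary share cannot be told apart. RNA integrity is argued against by the 3 prime minus 5 prime signal of control transcripts, which differed by 0.00061 between the female groups, under the SD of 0.10 between control populations. RNA input or labelling cannot be told apart from the treatment, because the poly-A controls were 0.45 higher in MLX females (6.6 to 6.96) than in control females (6.33 to 6.44), and a change of muscle with the MLX treatment stays open as untested.

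The 5 probe sets without a gene name that rose in MLX males are hard to explain by RNA of females. At the highest share of 1.73%, the rise would need female levels at least 3.85 above those of the highest female population, with the sexes put on 1 scale by their medians (SD between female populations at most 0.23). That share was taken from Yp1 alone, and another transcript could give a different one. It was also taken before the sexes were put on 1 scale, which would lower it and raise the female levels needed. In MLX male population 1, 0 arrays carried female transcripts. Yet 1641367_at stood there at 7.71, against 6.54 to 6.62 in control males, and 1637001_at at 5.80, against 4.61 to 4.73. The remaining probe sets, near background, also lay above control males there. These values, seen after the result, argue against RNA of females in that population. A general shift of the 4720 probe sets without a gene name is argued against by their median change of -0.014. A sequence variant under the probes and an effect of the MLX treatment stay open, and neither was tested. As a hypothesis, the change might belong to the treatment, and while the count of 5 fell to 0 without control population 3, their changes were then 0.64 to 1.06, against 0.69 to 1.07, with larger SE (0.09 to 0.14, against 0.08 to 0.12).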

How the results depend on the processing

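The settings that leave out male arrays with female transcripts or without poly-A controls, and the sex-bias classes made after centring, were chosen after the data were seen. Of the values of the main results under alternatives, 189 kept their side of the threshold, or a count within 1.5-fold, and 14 of them turned in direction with neither value past it. Another 46 were counts that moved further, 26 lost and 5 gained a call, and 5 reversed. For single genes and lists 1185 values kept their side, 64 of them with a turn of direction, 121 lost a call, 77 gained one and 1 reversed. Most genes and lists had no call in the main fit and could not lose one, so the 1185 do not measure how firm the calls are. In females CG10680, CG10514 and CG9897 each kept their call in 5 alternatives and lost it in 10, while 1641367_at in males kept it in 14 and lost it in 2. Where no cause is named below, the cause was not tested.

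For MLX against control in females, where 4 probe sets passed, the count was 0 with the dimmest 33.3% left out, with arrays centred on their medians, with the replicate block and with each sex fitted alone. It was 22 with array weights and 59 with all 24 arrays, which include the 4. Leaving out populations gave 0 to 1, with 1 without control population 2. In males, where 5 passed, the count was 1 with the dimmest 33.3% left out and 0 with 1 probe set per gene, a setting that drops probe sets without a name. It was 0 with the replicate block, 2 with each sex fitted alone, 13 with an intensity trend, 21 with all 24 arrays, 24 with array weights and 16 at a threshold of 0.1. Without the male arrays with female transcripts it was 9, of which 2 were among the 5. Leaving out populations gave 0 to 9, with 0 without control population 3 and 9 without MLX population 2. Averaged over the sexes, where 0 passed, the count was 4 with an intensity trend, 15 with a random population block, 222 with all 24 arrays, 2 at a threshold of 0.1 and 1 without the male arrays with female transcripts. Leaving out populations gave 0 to 2, with 2 without MLX population 2. For the difference in response, also 0, it was 2 with an intensity trend and 1 with array weights. The sex difference stayed between 11043 probe sets, with 1 probe set per gene, and 18007, with arrays centred on their medians.

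With an estimated correlation 0 lists passed in females, 0 in males and 0 for the difference in response, against 8, 4 and 4. Leaving out populations gave 3 to 8 lists in females, with 3 without control population 2 and 5 without MLX population 1. In males it gave 2 to 8, with 2 without control population 3 and 8 without MLX population 1. For the difference in response it gave 4 to 8, with 8 without control population 3, 7 without MLX population 2 and 8 without MLX population 3. Without the male arrays with female transcripts, 9 lists passed for the difference in response, and the testis list in males reversed to 0.065. No list past its threshold changed sign when arrays were centred or quantile normalized.

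The odds ratio of the X in males was 1.22 without the arrays that lacked poly-A controls and 1.11 to 1.62 without single populations, the lowest without MLX population 3. In females it was 0.754 to 0.955 without single populations, and 0.771, with Fisher's exact p under the threshold, without MLX population 3. Without single populations it was 0.767 to 1.04 for the average of the sexes and 0.842 to 1.30 for the difference in response, and without the arrays with female transcripts 0.84 and 1.18.

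Male-biased genes in females kept a mean of 0.039 with an estimated correlation but lost the call, and reversed to -0.00054 in classes of at least 4-fold and to -0.014 in classes made after centring. Female-biased genes in females kept -0.055 and lost the call with an estimated correlation. Male-biased genes in males gained a call without the arrays that lacked poly-A controls (-0.035) and in classes made after centring (-0.029), turned to 0.0074 without the arrays with female transcripts, and ranged from -0.035 to -0.0068 without single populations, the lowest without MLX population 1. Female-biased genes in males lost theirs with an estimated correlation (0.017), classes by adjusted p alone (0.0094), quantile normalization (0.016), without the arrays with female transcripts (0.0091), without the arrays that lacked poly-A controls (0.0040) and in classes made after centring (0.0061), and ranged from 0.0078 to 0.023 without single populations, the lowest without MLX population 3. Averaged male-biased genes lost theirs with an estimated correlation (0.011) and without the arrays that lacked poly-A controls (0.0018), and reversed in classes of at least 4-fold (-0.014), in classes made after centring (-0.021) and without MLX population 1 (-0.0017), in a range of -0.0017 to 0.023 without single populations. Averaged female-biased genes lost theirs with an estimated correlation (-0.019), and ranged from -0.034 to -0.0029 without single populations, the highest without control population 2. The difference in response lost its call with an estimated correlation in male-biased (-0.055) and female-biased genes (0.072), and in male-biased genes in classes of at least 4-fold (-0.027) and made after centring (-0.016).

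Signal over background limits the probe sets near 3 to 4 on the log2 scale, among them CG42594 and 3 of the 5 probe sets raised in males.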

Other observations

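All tests in this part other than the planned fits whose counts they restate were chosen after the result was seen.

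Other splits of the populations were fitted beside each comparison. With 10 splits of 6 populations the share cannot go under 0.05, and is never under 0.1. In females 4 probe sets passed, the highest of the other splits gave 14, and 3 of 10 splits gave as many as the real one. In males 5 passed and the highest other gave 2, so 1 of 10 gave as many. Averaged over the sexes 0 passed against a highest other of 1, and for the difference in response 0 against 5. There 10 of 10 gave as many in each, which a real count of 0 fixes in advance, so it decides nothing. For the sex difference, in a fit without the treatments, 16188 passed and the highest of the other splits gave 11818. Thus 1 of 100 gave as many, the smallest share that 100 splits allow. A split cannot separate sex from the different array medians of the sexes, so the size of this count stays tied to scaling. The 14 calls of another split of the females, over 3 times the real 4, may point to a structure of the samples, but what lies behind them was not tested.

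In males, small p-values may lie more often in probe sets without a gene name. At an unadjusted p of 0.001 or less were 26 of 4720 such probe sets (0.551%), 21 of them higher in MLX, and 48 of 13647 with 1 name (0.352%). Fisher's exact test gave an odds ratio of 1.57 (95% interval 0.933 to 2.58, p = 0.0818, adjusted over 3 comparisons 0.245), which leaves it open. In females the odds ratio was 0.677 (Fisher's exact p = 0.197).

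Genes of chromosome 4 might be shifted upward in MLX females. Their mean log2 change was 0.10 over 65 genes, with 41 above 0, and 0.09 over the 64 outside the muscle and vision lists. At an unadjusted p under 0.05, 18 were higher and 1 lower, with 0.32 ± 0.08 (SE, n = 3) for bt and 0.46 ± 0.12 for CG33521, chosen after their values were seen. The mean signal per population was 7.80 ± 0.04 (SD, n = 3) in MLX and 7.70 ± 0.04 in control females, without overlap (exact permutation p = 0.1, the smallest possible). Over 7 chromosomes the camera adjusted p was 9.8e-06 with the preset correlation but 0.688 with an estimated one, so a shift of the whole chromosome stays open. The poly-A controls were 0.45 higher in the same MLX females, also without overlap, so a difference in RNA input or labelling stays open too. A smaller share of ovary in whole MLX females was not tested for these genes and also stays open. In males the mean was 0.022 over the 65 genes.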
